A study of Homo sapiens with 50 samples.

How the data were processed

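The samples were genomic DNA from IMR90 cells, a line of human lung fibroblasts that stops dividing after a limited number of divisions (replicative senescence), grown at 3% oxygen. Lentiviruses carrying short hairpin RNAs (shRNAs), each built to lower the expression of 1 gene, were delivered at a multiplicity of infection of 0.3. Per the labels' design text, hairpins against regulators of chromatin were randomly divided among 5 initial pools with added control hairpins, among them lamin B1 and non-targeting ones, and the pools were combined pairwise into 10 paired pools, each infecting 1 plate. Cells were taken at population doublings (PD) 40, 45, 50, 55 and 60. The 50 samples were grouped by the population doubling in their labels, 10 plates per group.

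The deposited table held counts, per the file headers as sequence tags per hairpin, with 1 column per population doubling. Bowtie 1.0.1 is named in the submitters' processing notes; its settings, and how plates were combined into a column, are not given in the sources used here. Each column was therefore treated as the authors' pooled value, and columns per plate were not used here. With 1 column per population doubling there were no replicates, so no value below measures the spread between cultures. The table had 3443 hairpins, against 3455 in the design text; 3255 named 1 gene and 188 named several. Gene names are those of the table. Of 644 single names, 530 were current symbols in the RefSeq table of assembly GRCh38.p14, 106 were an older name of 1 gene, 6 an older name of several genes, and 2 had no match.

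Counts were scaled by column totals to CPM. Fold changes per hairpin were log2 of CPM plus a pseudocount of 1 over the same quantity at PD40, for hairpins with at least 10 counts in either column. This scale understates losses of hairpins that started low. Ratios carry exact 95% Poisson intervals, and counts under 3 were raised to a floor of 3 counts to give a bound. Tags were amplified by PCR without molecular identifiers, so intervals and floors cover counting error only. A linear trend of log2 abundance per population doubling was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM scaling, Benjamini-Hochberg adjustment, at least 10 counts in at least 2 columns). The error of that test is the departure of 5 columns from a straight line. DESeq2 1.42.0 gave an alternative.

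The gene-level value was the mean over hairpins naming only that gene, for 631 genes with at least 3 hairpins, with the SD over hairpins. Its percentile was taken among 10000 random sets of as many hairpins matched on 5 bins of PD40 abundance. The 2-sided share of sets as extreme, adjusted over genes by Benjamini-Hochberg, resamples hairpins within these columns and is not a replicate test. Gene lists were described by the percentile of their median among 10000 random lists matched on PD40 abundance. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Library diversity was computed after thinning each column to 8270745 tags.

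Tests, 19 gene lists with at least 3 measured genes and the rule for named genes were fixed before the data were examined. The rule took control targets, among them LMNB1 and the non-targeting hairpin, EP300 and CREBBP, then the 12 highest and 12 lowest gene means with at least 3 hairpins of the mean's sign. It also took up to 4 members per list with the largest absolute mean, and the 5 highest and 5 lowest hairpins. Genes outside it were chosen after their values were seen, and are identified as such. Lists for p300 and CBP and for each control had under 3 genes and were not tested as lists. Some genes that the rule took, or that passed a test, are not reported here.

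Both tests were tested on simulated data. For the trend over 5 columns, simulated at the fitted dispersion of 0.493, 51 of 200 slopes of 0.2 log2 per doubling were recovered among 3391 hairpins, with 1 false call, and 194 of 200 slopes of 0.4 among 3396 hairpins, with 6 false calls. Of 200 slopes of 0.1 at that dispersion, 0 were recovered among 3392 hairpins, with 0 false calls. At 10% of that dispersion 187 of 200 slopes of 0.1 were recovered among 3401 hairpins, with 8 false calls. For slopes of 0.2 it was 200 of 200 among 3398, with 12, and for 0.4 200 of 200 among 3399, with 5. Only the 200 hairpins changed in each simulation, as many rising as falling, whereas in the data most hairpins fell relative to the column total. The counts of false calls therefore do not carry over to the data. For the gene-level value over 631 genes, a shift of 4 log2 units on every hairpin of 20 genes was recovered for 5 of them, and a shift of 2 for 0 of them. The gene-level comparison therefore had little power.

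Alternatives covered scaling, pseudocounts, count minimums, the tool, end points and left-out columns or hairpins. Added after the data were seen were PD45 and PD50 as end points of genes and lists, scaling without the 50 most abundant hairpins, 100000 random sets, random sets matched also on 8 series of hairpin catalogue numbers (strata of at least 20 hairpins), and removal of 1 hairpin from each same-gene pair with matching counts. A pair matched when each hairpin had at least 100 tags at PD40 and 300 later, and a chi-square test for equal counts over the 5 columns gave p over 0.05.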

Results

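The screen asked which regulators of chromatin limit the replicative lifespan of fibroblasts: a cell whose hairpin lowers such a gene should outgrow its neighbours on serial passage. Abundance of 3443 hairpins was read from the integrated DNA at 5 population doublings. The authors' pooled columns held 8626437 tags at PD40, 8782622 at PD45, 8479667 at PD50, 11505688 at PD55 and 8270745 at PD60. There was 1 column per time and no replicate.

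The library narrowed at every step. At equal depth, 3440 hairpins had at least 1 tag at PD40, 3393 at PD45, 3113 at PD50, 2702 at PD55 and 1924 at PD60. The effective number of hairpins, the exponential of Shannon entropy, was 1308 at PD40, 594 at PD45, 245 at PD50, 81.0 at PD55 and 51.1 at PD60. The 35 most abundant hairpins, 1% of the library, held 19.3% of tags at PD40 and 85.4% at PD60. At PD40 the top 282 hairpins held 50% of tags, and at PD60 the top 10 did.

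**Figure D1:**
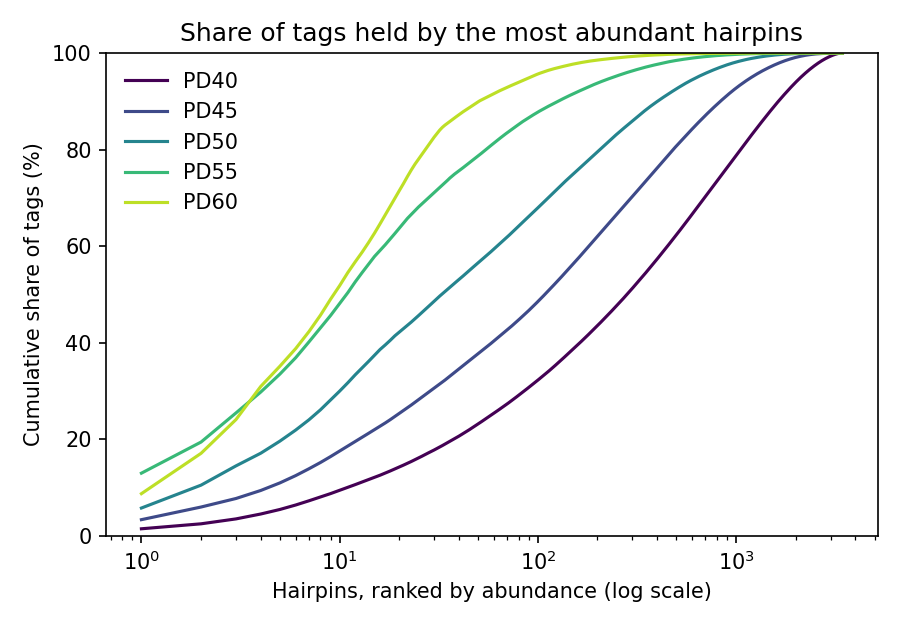
Cumulative share of tags (%) against hairpins ranked by abundance (log axis), 1 line per pooled column. The 35 most abundant hairpins held 19.3% of tags at PD40 and 85.4% at PD60.

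Hairpins against HDAC2, SETD2, TSSK6, TGM2 and HIST1H2AH, 1 for each gene, had the highest PD60 to PD40 ratios. None of these genes was among the 7 of 631 with 2 or more hairpins over 2-fold higher. For SETD2, 4 of 5 hairpins were over 2-fold lower. HDAC2 encodes a histone deacetylase and SETD2 the methyltransferase that trimethylates lysine 36 of histone H3. HDAC2 hairpin TRCN0000004823 went from 2451 to 231551 tags, a ratio of 98.5 (95% counting interval 94.7 to 103). The ratios were 82.6 (79.9 to 85.4) for SETD2 TRCN0000003033, 72.2 (70.8 to 73.6) for TSSK6 TRCN0000037459, 55.0 (53.2 to 56.9) for TGM2 TRCN0000000241 and 53.4 (51.6 to 55.3) for HIST1H2AH TRCN0000106761. The TSSK6 hairpin was the most abundant at PD60, with 719862 tags. It was followed by CDKN2A TRCN0000010482, against the locus of the cell cycle inhibitor p16, with 691448 tags and a ratio of 8.22. The CDKN2A hairpin, named after its values were seen, was already at rank 3 at PD40, with 87712 tags. It had 10170, 12940, 17360 and 11000 CPM up to PD55 and 83600 at PD60, so its ratio rested on the last column.

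On the log2 scale with its pseudocount, the lowest hairpins targeted PIK3CB, NAP1L4, PIK3CA, CHMP6 and ATR. PIK3CB TRCN0000009860 went from 18444 tags to 4, 4421-fold lower. NAP1L4 TRCN0000151475 was 3588-fold lower, CHMP6 TRCN0000155260 2501-fold, PIK3CA TRCN0000010406 1705-fold and ATR TRCN0000010300 1656-fold. These 5 hairpins started at ranks 41 to 95 of PD40 abundance and ended at 4 to 13 tags. The counting intervals of their ratios overlap. Raw ratios give another order, with the 1497 hairpins at 0 tags at PD60 lowest. EP300 TRCN0000039884, with 1 tag at PD60, had a ratio of 0.000306 (7.76e-06 to 0.00171). This ratio lay between those of NAP1L4 TRCN0000151475 and CHMP6 TRCN0000155260. Another NAP1L4 hairpin, TRCN0000154499, chosen after its values were seen, was 15.3-fold higher, with 578351 tags at PD60. Of 8 ATR hairpins, 7 were over 2-fold lower and 1 over 2-fold higher. Together the ATR hairpins held 0.497% of tags at PD40 and 1.82% at PD60.

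Of 3418 hairpins, 78 (2.28%) were over 2-fold higher at PD60 than at PD40, 3257 (95.3%) over 2-fold lower and 83 within 2-fold; 1497 were at 0. The median log2 fold change was -5.86. The 78 hairpins held 8.68% of PD40 tags and 90.0% of PD60 tags. Of these, 44 were also over 2-fold higher at PD55, and 29 were so at no earlier time. With TMM scaling, whose factors ran from 8.76 at PD40 to 0.0774 at PD60, the median was -1.86, with 18.7% of hairpins higher and 64.7% lower. Directions below are therefore relative to the column total unless scaling is named.

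Starting abundance went with both outcomes. In the lowest quintile of PD40 abundance 84.4% of hairpins were at 0 at PD60 and 0.146% were over 2-fold higher. In the highest quintile these were 1.46% and 6.15%. Hairpins of the lowest quintile started at 10 to 334 tags and those of the highest at 3022 to 123277. A smaller fall therefore sufficed to reach 0 in the lowest quintile.

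SETD2 TRCN0000003033 rose in the test for a linear trend, with 3475, 7006, 7499, 69351 and 275135 tags at the 5 times. HDAC2 TRCN0000004823 passed too, but its 2451 tags at PD40 were 2453, 583 and 737 at the next times and 231551 at PD60, so the size of its slope rested on the last column. With TMM scaling the adjusted p, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was 0.006295 for the HDAC2 hairpin and 0.003589 for the SETD2 hairpin, each at a slope of 0.66 log2 per doubling. Scaled to total counts, their slopes were 0.32 and 0.31, with edgeR adjusted p of 0.005979 and 0.0005002. Without PD60 the TMM slopes were 0.18 and 0.59. For PIK3CB TRCN0000009860 the TMM slope was -0.25 with an edgeR adjusted p of 0.008582, which was 0.06233 with DESeq2's size factors. Of the 78 hairpins higher at PD60, 27 rose with total counts, while with TMM, whose factors raised every slope, all 78 had an adjusted p under 0.05. Of 3116 hairpins tested with TMM scaling, 1304 passed, 354 rising and 950 falling. With scaling to total counts 27 rose and 2679 fell, with DESeq2's size factors 379 rose and 405 fell, and with DESeq2's Wald test 538 rose and 199 fell. Without PD40 249 rose and 270 fell, without PD45 223 and 354, without PD55 225 and 639, and without PD60 556 and 904, so the balance of directions moved with scaling, test and columns. The test measured departure from a straight line over 5 columns, not spread between cultures.

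Hairpins against the control target LMNB1 differed from each other. Of 5 hairpins against LMNB1, the gene of lamin B1, whose loss hastens senescence, TRCN0000029272 had a ratio of 20.7 (20.2 to 21.2) and the others were 18.8-fold to 419-fold lower. The non-targeting hairpin went from 4562 to 39 tags, 112-fold lower (percentile 34.3 among hairpins). The mean log2 fold change was -3.71 for LMNB1 (SD 4.65, 5 hairpins, percentile 87.6). With TMM scaling it was 2.77, and 0.013 for the non-targeting hairpin.

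EP300 encodes the histone acetyltransferase p300 and CREBBP its paralog CBP. Of 8 EP300 hairpins, TRCN0000009884 had a ratio of 3.41 (3.39 to 3.44) and TRCN0000009882 of 3.24 (3.15 to 3.34). TRCN0000009884 had 10310, 14160, 12030 and 10440 CPM up to PD55 and 35190 at PD60, so its ratio rested on the last column. TRCN0000009882 peaked at 11330 CPM at PD55 and was at 2317 at PD60. The edgeR adjusted p for the trend of these 2 hairpins was 0.003967 and 0.004878 with TMM scaling but 0.2586 and 0.1097 with total counts. The most abundant hairpin of the library at PD40, EP300 TRCN0000009883 with 123277 tags, went to 2944, 40.1-fold lower. The mean for EP300 was -4.32 (SD 3.87, percentile 85.1), and its hairpins together held 2.80% of tags at PD40 and 3.79% at PD60. Of their 313537 tags at PD60, 291065 were those of TRCN0000009884. All 5 CREBBP hairpins were over 2-fold lower (mean -4.92, SD 0.95, percentile 46.1).

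**Figure D2:**
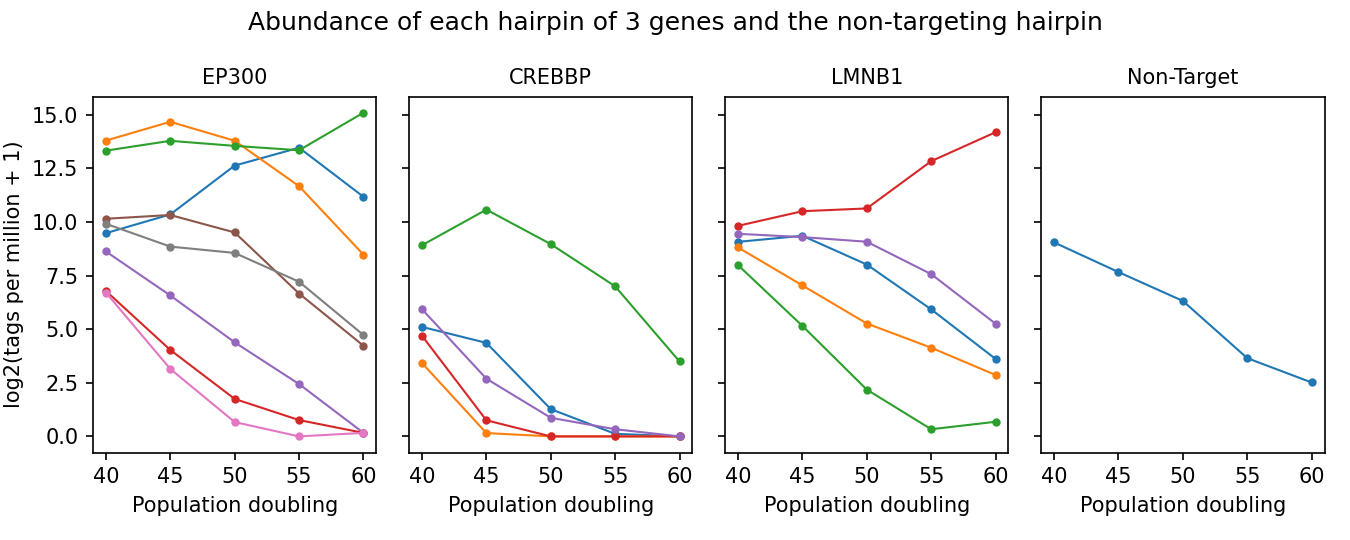
Abundance, as log2 of CPM plus 1, against population doubling, 1 line per hairpin. For EP300 and LMNB1, 2 and 1 hairpins were over 2-fold higher at PD60 than at PD40, and for CREBBP and the non-targeting hairpin 0 were.

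RPA1 (-1.55) and ACTL6A (-1.65), named after their values were seen, had the highest gene means at PD60. The rule left them out because each had 2 hairpins of the mean's sign. As no gene mean was above 0, that sign was a fall from PD40. The rule therefore asked for at least 3 hairpins that fell, which is no mark of support for a high mean. The highest means with at least 3 such hairpins were those of HIST3H2BB (-1.82, SD 1.09), AOF2, the older name of the lysine demethylase KDM1A (-2.08, SD 5.43), H2AFZ, which encodes the histone variant H2A.Z (-2.16, SD 3.33), PADI4 (-2.33, SD 5.07) and MEN1, which encodes menin (-2.34, SD 3.11, 8 hairpins, percentile 99.8). HIST1H2AC (-2.38), HIST4H4 (-2.46), BRD2 (-2.50), H2AFX (-2.54), IKBKE (-2.54), PRDM16 (-2.68) and SETD2 (-2.72) followed. For SETD2 1 of 5 hairpins was over 2-fold higher, and for AOF2, H2AFZ, MEN1 and IKBKE 2 were.

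The lowest means were those of CYP2B6 (-8.59, SD 1.73, percentile 0.070), NPM3 (-8.51, SD 0.58, percentile 0.12) and CXXC1, which encodes the CpG-binding subunit of the SETD1 complexes (-8.40, SD 0.17, percentile 0.25). ADAR (-7.94), ING3 (-7.84), SMC3 (-7.81), RING1 (-7.64), SMC4 (-7.61), PIK3R2 (-7.58), PCGF2 (-7.53), USP22 (-7.43) and MORF4L1 (-7.40) followed. These means depend on starting abundance, which bounds how far a lost hairpin can go.

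Of 631 genes, 0 had an adjusted share under 0.05 at PD60; 46 had an unadjusted share under 0.05, against 31.6 expected. The smallest adjusted share was 0.379. No gene mean was above 0, 64 genes had at least 1 hairpin over 2-fold higher, and 7 had 2 or more (AOF2, DDB1, EP300, H2AFZ, IKBKE, MEN1 and TGM1). DDB1 and TGM1 are named after their values were seen.

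As no gene mean was above 0, the members with the largest absolute mean, named here for each list, are its lowest. For their starting abundance they need not be low: CDYL stood at percentile 44.3 and CLOCK at 41.0. Among enzyme families that write or remove histone acetylation, medians lay within those of random lists. The histone acetyltransferases had a median of -5.44 (18 genes, percentile 71.7), with CDYL at -6.44, ATF2 at -6.37, CLOCK at -6.32 and KAT2B at -6.24; 5 of 99 hairpins were over 2-fold higher. The histone deacetylases had -5.64 (18 genes, percentile 33.1), with HDAC11 at -6.98, SIRT2 at -6.77, SIRT6 at -6.63 and SIRT3 at -6.60. The bromodomain readers had -5.88 (19 genes, percentile 32.4), with BAZ2A at -7.01, BRWD1 at -6.89 and BAZ1A at -6.67.

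The arginine methyltransferases had the lowest percentile of the 19 lists, 3.15 (median -6.50, 8 genes), with PRMT7 at -7.07, PRMT8 at -6.76, PRMT5 at -6.60 and PRMT2 at -6.59. The H3K4 methylation group had -5.19 (17 genes, percentile 82.0), with CXXC1 at -8.40, PAXIP1 at -7.00, SETD1A at -6.49 and MLL2 at -6.15. Adjusted over the list alone, 2 of its genes passed, at opposite ends: CXXC1 (percentile 0.25) and MEN1 (-2.34, percentile 99.8). The H3K9 methylation and heterochromatin group had -5.82 (11 genes, percentile 49.6), with ATF7IP at -7.34, EHMT1 at -7.14, SETDB2 at -6.38 and TRIM28 at -6.31. The group for H3K36, H3K79 and H4K20 had -5.51 (10 genes, percentile 39.9), with SUV420H2 at -6.99 and WHSC1L1 at -6.70. The histone demethylases had -5.64 (19 genes, percentile 31.3), with JMJD2D at -7.23 and JMJD1A at -7.17. The DNA methylation group had -5.21 (14 genes, percentile 85.2), with DNMT3B at -7.13 and DNMT3L at -6.28.

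At PD60 the Polycomb lists had medians within those of random lists, and at PD50 and PD55 their percentiles were lower. For the complex that methylates H3K27 (PRC2), 0 of 42 hairpins were over 2-fold higher (median -5.81, percentile 31.8), with SUZ12 at -7.38 and RBBP7 at -6.79. For PRC1 it was 0 of 90 (median -5.81, percentile 19.8), with RING1 at -7.64, PCGF2 at -7.53, L3MBTL2 at -7.06 and BMI1 at -6.85. PRC2 and PRC1 stood at percentiles 0.85 and 1.06 at PD50 (unadjusted shares 0.017 and 0.021, both 0.203 adjusted) and at 1.74 and 1.5 at PD55 (both 0.333 adjusted). With the mean over genes in place of the median, PRC1 at PD60 stood at 1.32 (adjusted share 0.505). For the ISWI, CHD, NuRD and INO80 remodellers it was 0 of 123 (median -5.74, percentile 19.9), with CHD5 at -6.89 and CHD2 at -6.80. Tested as the share of hairpins over 2-fold higher, these 3 lists had 2-sided shares of random lists of 1, 0.221 and 0.143, each 1 after adjustment. The SWI/SNF remodellers had the highest percentile, 95.7 (median -4.98, 15 genes, 4 of 74 hairpins higher, 1 gene adjusted over the list alone), although ARID1A stood at -6.74 and SMARCC2 at -6.14.

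The histone chaperones had a median of -5.09 (19 genes, percentile 91.0), with ASF1B at -6.66 and RSF1 at -6.53. The senescence effectors had -5.18 (10 genes, percentile 88.7), with RBL1 at -6.91, ATM at -6.78, RB1 at -5.91 and ATR at -5.58. Cell division and replication genes had -5.07 (7 genes, percentile 79), with PCNA at -6.28. The ING family had -6.19 (4 genes, percentile 25.9), with ING3 at -7.84 and ING1 at -6.34. The ubiquitin group had -5.34 (7 genes, percentile 55.2), with USP22 at -7.43, and the SAGA, ATAC and TIP60 subunits -6.16 (8 genes, percentile 17.0), with MORF4L1 at -7.40. Of the 19 lists, 0 had an adjusted or an unadjusted share under 0.05, and the smallest adjusted share was 0.787.

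At earlier times RET, which encodes a receptor tyrosine kinase, had a mean of -2.45 over 15 hairpins at PD45, against a median of -1.63 over genes, and -4.79 at PD50. SMARCB1, a SWI/SNF core subunit, stood at -3.24 (SD 1.04, 8 of 8 hairpins over 2-fold lower) at PD45. RET and SMARCB1 are named after their values were seen.

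With 10000 random sets, as at PD60, 0 of 631 genes had an adjusted share under 0.05 at PD45, PD50 or PD55; 64, 48 and 52 had an unadjusted share under 0.05. The smallest share was the smallest that 10000 sets can give. With 100000 sets, added for that reason after those counts were seen, 4 genes passed at PD45, RET and SMARCB1 among them, 3 at PD50, RET among them, 1 at PD55 (RET) and 0 at PD60. The calls at PD45 ranged from 0 to 5 over 9 further settings. With 1 hairpin of each matching pair and sets matched also on catalogue series, 0 genes passed at PD45 (adjusted share 0.319 for RET and 0.390 for SMARCB1), while 3 passed at PD50, RET among them, and 0 at PD55, where RET had an adjusted share of 0.0505.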

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

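No paired analysis was possible because each column was pooled over the 10 plates. Comparisons of PD45, PD50, PD55 and PD60 with PD40 by a test over plates were not run for the same reason. Scaling to the non-targeting hairpin was not run, since it had 39 tags at PD60, under the 100 required. Chosen after seeing the data were random sets beyond 10000 and all settings run on them, catalogue series, matching pairs, several-gene hairpins, counts of at least 3, and scaling without the 50 most abundant hairpins. So were PD45 and PD50 as end points of genes and lists, and PD45, PD50 and PD55 as end points of hairpins. Unless a reason is given, the cause of a change was not tested.

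Trend calls, 1304 with 354 rising and 950 falling, were 2706 (27 rising, 2679 falling) with total counts, 784 (405 falling) with DESeq2's size factors and 737 (538 rising, 199 falling) with DESeq2's Wald test. Leaving out 1 column gave 519 to 1460 calls, 223 to 556 rising and 270 to 904 falling. Without PD40 there were 519 calls and without PD45 577, on 2419 and 2427 tested hairpins; without PD55 there were 864 (225 rising), and without PD60 556 rising.

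For the fold change per hairpin (median -5.86, 78 higher), TMM scaling gave a median of -1.86, 640 hairpins or 18.7% higher and 64.7% lower. A pseudocount of 10 gave a median of -3.22 and 91.9% lower, and the mean of the late against the mean of the early columns gave 93.6% lower. Scaling without the 50 most abundant hairpins gave 214 or 6.26% higher and 88.1% lower. At PD45 the median was -1.63 (196 or 5.73% higher, 63.2% lower), at PD50 -3.46 (169 or 4.94% higher, 81.9% lower) and at PD55 2.92% were higher and 91.7% lower. Of the 80 further values for 10 named hairpins, 57 moved by under 1 SD over hairpins and 0 changed sign.

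TMM scaling turned the signs of the controls, with LMNB1 at 2.77 and the non-targeting hairpin at 0.013, and a pseudocount of 10 put the last at -5.19. Requiring 10 tags left 1658 hairpins detected at PD55 and 984 at PD60.

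Calls per gene at PD60 were 0 under all alternatives run, and so were calls of the 19 lists fixed before the data were examined, of which up to 2 had an unadjusted share under 0.05 in a setting. Of the further values for 97 named genes, 899 moved by under 1 SD over hairpins, 163 by more and 5 changed sign. The second-best hairpin was above 0 for AOF2 (1.04), H2AFZ (1.16), MEN1 (1.11), IKBKE (1.81) and EP300 (1.70). With 100000 random sets 4 genes passed at PD45, 3 at PD50 and 1 at PD55. The 4 at PD45 became 0 with medians over hairpins, 1 with several-gene hairpins and 2 without the most extreme hairpin (RET among them). They became 1 with sets matched on catalogue series, and 0 when 1 hairpin of each matching pair was also removed, which left 3 at PD50 and 0 at PD55. Depth limits late values: the median hairpin had 1 tag at PD60.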

Other observations

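In this part the tests on catalogue series, matching pairs and the change from PD55 to PD60, and the lists added below, were chosen only after the results were seen. Among 8 added lists, the H2A histone family had a median log2 fold change of -4.89 at PD60 (15 genes, percentile 98.0), with 5 of 66 hairpins over 2-fold higher, and the replication and transcription machinery -4.92 (25 genes, percentile 97.9). Core histones and variants stood at percentile 70.6, PI3K and mTOR pathway genes at 36.7, SMC, cohesin and condensin genes at 10.1, NF-kappaB genes at 89.1, AP-1 and MYC genes at 94.8 and HMG proteins at 25. After adjustment 0 of the 8 had a share under 0.05 at PD60. At PD45 the replication and transcription machinery stood on the other side, at -2.43 against -1.90 for random lists (percentile 0.27, share 0.048 adjusted over the 8 lists at that time), and at PD50 at percentile 32.4. HMG proteins stood at 96.9, 98.2 and 95.8 at PD45, PD50 and PD55, and AP-1 and MYC genes at 1.52, 22.8 and 74.9, and neither list had an adjusted share under 0.05. For the H2A family the percentiles at these times were 91.07, 91.45 and 58.82, with no adjusted share under 0.05.

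Some hairpins of 1 gene had matching counts. Of 2565 same-gene pairs with enough tags, 9 (0.351%) had counts that matched in 1 chi-square test over the 5 columns together, against 776 of 1864713 pairs of different genes (0.0416%). RET hairpins TRCN0000000405 and TRCN0000010252 had 5462 and 5567 tags at PD40 and 1656 and 1697 at PD60. Other pairs were those of AKT2, CDKN1A, CDY1, DAPK3, SATB1 and TSPYL2. Hairpin sequences were not used here, so whether such a pair shares 1 sequence was not tested.

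Single hairpins expanded at PD60 while others of the same gene were lost. Starting abundance may account for part of this: hairpins over 2-fold higher were 4.67 times as frequent in the top quintile of PD40 abundance as in the rest. Takeover by lineages regardless of target would leave hairpins of 1 gene no more alike than shuffled ones, but their between-gene share of variance, 23.2%, lay at percentile 99.9 of 1000 shuffles. That bound does not allow for series of constructs: with shuffles within catalogue series and 1 hairpin of each matching pair it was at 99.4, too close to the bound of 99 for 1000 shuffles, so both explanations stay open. Knockdown of the target stays open too, since 7 genes had 2 or more higher hairpins and the 95th percentile of shuffles was 7.

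At PD45 hairpins of 1 gene resembled each other more clearly. With matching pairs removed and series matched, the between-gene share was 25.3%, against a 99th percentile of 21.9% for the shuffles. At PD50 the share was 23.63% against 21.95%, and at PD55 22.87% against 21.89%. The same test at PD60 gave percentile 99.4. The excess may reflect effects of the target genes that later takeover hides, which is a hypothesis from these data. Genes with 2 or more hairpins over 2-fold higher gave no such excess at PD45: 25, against a median of 22 for the shuffles (percentile 76.9). At PD50 there were 21, against a median of 15 and a 95th percentile of 20.05 (percentile 95). Without matching on series, PD50 stood at percentile 86.2. At PD55 there were 6, against a median of 6.

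The 2 most abundant hairpins at PD40 were EP300 hairpins, from a series of neighbouring catalogue numbers between 9600 and 11000. A candidate explanation is that this series started high: its 108 hairpins of other genes had a median PD40 percentile of 88.0. No biological explanation was tested, since PD40 is the earliest column.

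Many leading hairpins changed between PD55 and PD60. Of the 50 most abundant at PD55, 35 (70.0%) changed over 2-fold with separate counting intervals, 27 of them lower; of the 50 most abundant at PD60, 36 changed over 2-fold, 26 of them higher. Leaders at either time are favoured to be lower at the other, so these splits show no direction for the library. Counting error is too small to be the source of the 35: of 1000 simulated pairs of columns with equal shares, the highest number was 0. Each of the 50 had at least 32714 tags at PD55, so this outcome was near certain beforehand and bears on no other source. Bounds of 50% and 75% set first on the share had allowed more change than counting error gives. Unequal shares of the plates could move the leading hairpins, and the table has 0 columns per plate to show it. Amplification error was not tested. For the trend over population doublings, 1 of the 60 distinct orders of the columns, the real one, gave as many as 1304 calls and the highest other gave 828. That goes against a random order of the columns and no more. The columns are serial passages of the same plates, so any change that builds up, such as takeover by lineages, also favours the real order. The comparison therefore cannot tell such changes from effects of the hairpins.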
